A study of Mus musculus with 8 samples.

How the data were processed

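RNA was measured in 8 samples of mouse satellite cells, 4 given DMSO and 4 given sal003. Per the labels' protocols, total RNA was isolated with a column kit, ribosomal and mitochondrial RNA was depleted, and stranded libraries were made with the SMARTer chemistry and sequenced on an Illumina MiSeq. The labels give the sal003 dose as 10 µM in the design text and the sample attributes and as 10 mM in the treatment protocol; 10 µM is used here. The authors deposited 1 table of whole-number counts per gene, with Ensembl identifiers and symbols, in which no row lacked a gene. Per the submitters' processing notes, Trimmomatic 0.32, STAR 2.3.0e, featureCounts 1.4.4 and the mm10 build were used. Settings for strand, reads with several alignments and overlapping genes are not given in the sources used here, so values of overlapping or antisense genes, pseudogenes and near-identical family members are uncertain. Of the counts from 1 to 20, 80.5% ± 3.41 were even in DMSO and 80.2% ± 0.865 in sal003 (SD over libraries, n = 4), where whole fragments would give about as many odd as even values. An alternative with counts divided by 2 was therefore added after seeing the data. The labels describe no molecular identifiers, so precision from depth covers counting error only.

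Depth ranged from 32753929 to 40234107 counts per library. Such totals are high for the MiSeq that the labels name, so the instrument stays uncertain. All 8 columns were matched to samples by name. Replicate pairs were compared by a chi-square of their counts, and each pair differed far beyond counting noise (at least 25.5 per degree of freedom), so no library was treated as a duplicate. Coordinates and gene types come from the GENCODE M21 annotation of mm10, in which 37607 of the 39017 identifiers (96.4%) were found.

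In R 4.3.3, counts were analysed with edgeR 4.0.16. Genes were kept with filterByExpr by condition (minimum count 10, minimum total 15), libraries were scaled by TMM, and sal003 was compared with DMSO in a robust quasi-likelihood fit with condition as the only term. Tests were two-sided with Benjamini-Hochberg adjustment, and adjusted p below 0.05 was the threshold. The SE of a log2 fold change is its size divided by the square root of the quasi-likelihood F. CPM are TMM-scaled. Gene lists were tested with camera from limma 3.58.1 at a preset correlation of 0.01, adjusted over 29 lists, of which 5 were primary (spindle, stress response, satellite cell identity, commitment, sarcomere) and the rest context. The value of a list is the median log2 fold change of its tested members. Members past the threshold were counted over all tested genes and adjusted over the list alone. With the correlation estimated per list, 7 of the 14 list calls held: replication, spindle, G2/M, p53, commitment, sarcomere, and smooth muscle and pericyte. The self-contained test fry asks whether the genes of a list move one way on balance and does not compare them with other genes.

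Except where said otherwise, the tests, samples, lists and naming rule were set before the data were examined. The rule names 13 fixed genes (Tacc3, Pax3, Pax7, Myf5, Myod1, Myog, Eif2s1, Atf4, Ddit3, Ppp1r15a, Ppp1r15b, Cdkn1a and Mki67), the 8 largest changes in each direction among genes past the threshold with a symbol, expression at or above the median and no overlap between conditions, predicted and clone-named genes excepted, and up to 4 members of each list past the threshold in order of p. The text names only part of the genes under the rule. Genes named outside the rule are said to be so.

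Alternatives were DESeq2 size factors and upper-quartile scaling in edgeR, no filter, a filter of 10 CPM in 4 libraries, removal of mitochondrial, ribosomal RNA and the 20 most abundant genes, a replicate block, leaving out each library in turn, the Wald test of DESeq2 1.42.0 with undefined adjusted p left undefined, limma-voom with sample quality weights, an adjusted p of 0.01, a test against a 1.5-fold change, removal of a smooth trend in GC content or transcript length, camera with estimated correlation, fry, and lists without shared members. Halved counts and protein-coding genes alone were added later. GC content and length were known for 98.4% of tested genes.

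The fit was tested on simulated counts for this comparison, in which 200 genes were changed and 15125 passed the filter. It recovered 11 of 67 genes changed 1.5-fold, 29 of 67 changed 2-fold and 39 of 66 changed 4-fold, and called 8 of 14915 unchanged genes. Of the lists, the 1 raised by 1.5-fold was recovered and 0 of the other 28 were called. The simulated genes varied independently of each other, whereas the correlation estimated for the sarcomere list was 0.27. The simulation therefore cannot show how often lists of correlated genes are called falsely. It also changed far fewer genes than the 3594 called in the data and gave all libraries the same spread. Its recovery rates are thus not those of the real comparison. A planted GC trend gave 5059 calls without and 1 call with the trend correction.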

Results

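Gene expression was measured by RNA sequencing in satellite cells, the stem cells of skeletal muscle, taken from diaphragm and abdominal muscle of adult mice that carry a green fluorescent protein reporter at 1 allele of Pax3. The cells were plated at 7500 per 35 mm dish and kept for 4 days in 10 µM sal003, a compound that blocks dephosphorylation of the translation factor eIF2α, or in its vehicle DMSO. There were 8 libraries, 4 per condition, and the table held 39017 genes. Total counts ranged from 32753929 to 40234107 per library in DMSO and from 37248830 to 39378523 in sal003. Between 16561 and 18076 genes had at least 1 count in 7 of the libraries, and 14437 in DMSO replicate 2. Spearman correlation across the tested genes ran from 0.977 to 0.982 within sal003 and from 0.977 to 0.979 among DMSO replicates 1, 3 and 4. DMSO replicate 2 reached at most 0.949 with another DMSO library, and correlations between the conditions lay between 0.924 and 0.957. The labels do not say whether the replicates came from separate animals or cultures, so the p-values measure only the spread between these libraries.

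**Figure D1:**
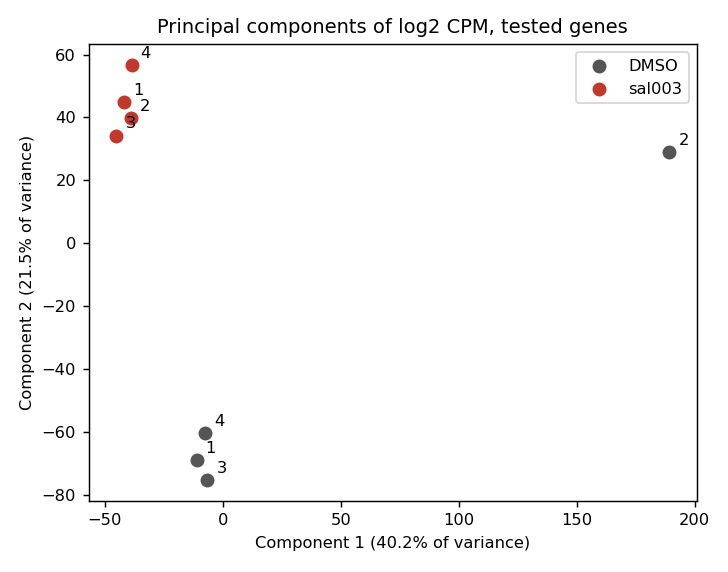
Principal components of log2 CPM over the tested genes, one point per library, numbered by replicate, DMSO in grey and sal003 in red; each axis gives its share of the variance. The first component (40.2%) separates DMSO replicate 2 from the other libraries, and the second (21.5%) separates DMSO replicates 1, 3 and 4 from the 4 sal003 libraries. On the second component DMSO replicate 2 lies nearer to the sal003 libraries than to the other DMSO libraries.

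The comparison of sal003 with DMSO addresses which transcripts differ between satellite cells cultured with the inhibitor and with its vehicle. Transcripts of DNA replication and mitosis were higher in sal003, while those of the contractile apparatus and of myogenic commitment were lower. Of 15816 genes tested with edgeR, 1671 were higher and 1923 lower in sal003. The higher genes had a median log2 fold change of 0.68 and the lower genes of -0.91. A 4-fold or larger difference was estimated for 333 of the lower genes and 13 of the higher ones. The 2 groups of libraries did not overlap at 3302 of the 3594 changed genes and at 26.8% of all tested genes, where chance gives 2.86%. Without DMSO replicate 2, 2219 genes were higher and 2252 lower. Against a change of at least 1.5-fold, rather than against no change, 266 genes were higher and 737 lower.

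Tacc3, the spindle gene named in the series title, was higher in sal003, at 81.5 ± 4.29 CPM in DMSO and 146 ± 2.76 CPM in sal003 (SD, n = 4; ENSMUSG00000037313, chromosome 5, 33658128 to 33678995, plus strand of mm10). Its log2 fold change was 0.84 ± 0.09 (SE; edgeR adjusted p = 4.01e-06), with all 4 sal003 libraries above all 4 DMSO libraries. Of the other members of the family, singled out after their values were seen, Tacc2 fell by 0.59 on the log2 scale (edgeR adjusted p = 0.00101), and Tacc1 had a log2 fold change of -0.08 ± 0.11 (adjusted p = 0.720). These are transcript levels, and translation was not measured in the libraries.

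Of 58 genes of the mitotic spindle and centrosome, 48 rose, 1 fell, which was Tacc2, and 9 did not pass the gene test (51 higher and 1 lower adjusted over the list alone). The list's median log2 fold change was 0.93 (camera adjusted p = 6.50e-31). The kinesin Kif15 went from 57.7 ± 8.56 to 144 ± 12.9 CPM, the checkpoint kinase Bub1b from 81.8 ± 8.84 to 175 ± 8.56 CPM and the centromere protein Cenpf from 206 ± 21.7 to 378 ± 13.6 CPM (SD, n = 4). Tpx2, which activates Aurora A on the spindle, had a log2 fold change of 0.82 ± 0.08. Among 37 further regulators of G2 and mitosis 28 rose and 0 fell (29 higher and 0 lower adjusted over the list alone), with a median of 0.82 (camera adjusted p = 1.88e-17). They included the transcription factor Mybl2, at 1.48 ± 0.12, and the topoisomerase Top2a, at 1.16 ± 0.10. The proliferation marker Mki67 stood at 882 ± 181 CPM in DMSO and 1866 ± 86.8 CPM in sal003 (edgeR adjusted p = 9.28e-06). Of 58 genes of DNA replication and the G1/S transition 51 rose and 1 fell (52 higher and 1 lower adjusted over the list alone), with a median of 0.999 (camera adjusted p = 4.84e-33). Uhrf1, a partner of the maintenance DNA methyltransferase, went from 85.8 ± 5.49 to 209 ± 0.889 CPM, Atad2 had a log2 fold change of 1.28 ± 0.09, and Mcm6, a subunit of the replicative helicase, of 1.16 ± 0.09. The member that fell, Ccnd3, encodes cyclin D3 (log2 fold change -0.36 ± 0.10, adjusted p = 0.0138, chosen after its value was seen), and its adjusted p was 0.0628 without sal003 replicate 1 and 0.0531 without sal003 replicate 3. The calls on the spindle, G2/M and replication lists held with an estimated correlation between genes (adjusted p = 0.00887, 0.00133 and 0.00133).

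**Figure D2:**
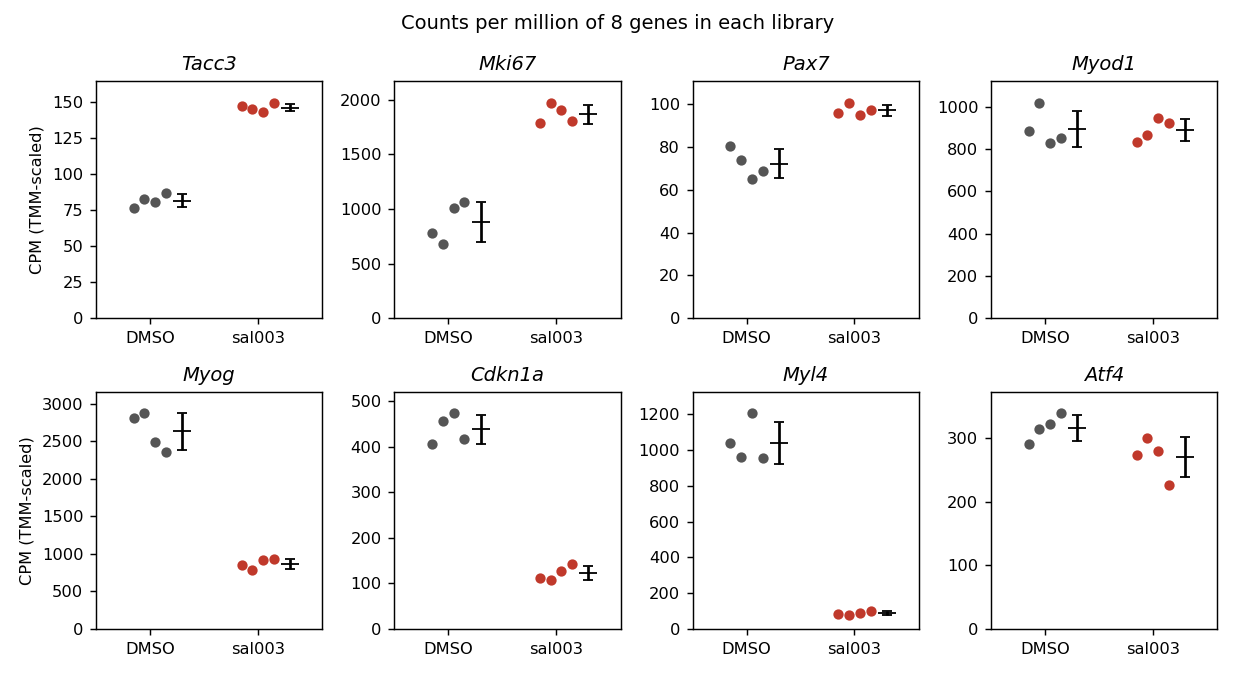
TMM-scaled CPM of 8 genes, one panel each on a linear axis from 0, with a point per library (4 DMSO in grey, 4 sal003 in red) and the mean ± SD beside each group. All sal003 libraries lie above all DMSO libraries for Tacc3, Mki67 and Pax7 and below them for Myog, Cdkn1a and Myl4, while the groups overlap for Myod1 and Atf4.

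The largest shift was in the sarcomere. Of 66 genes of the contractile apparatus tested, 0 rose and 61 fell (62 lower adjusted over the list alone), and the median log2 fold change was -2.28 (camera adjusted p = 1.75e-138; 0.00160 with an estimated correlation). The list took 9.75% ± 1.18 of all counts in DMSO and 3.05% ± 0.172 in sal003 (SD, n = 4). Myl4, an embryonic and atrial myosin light chain, went from 1039 ± 116 to 88.4 ± 10.4 CPM (ENSMUSG00000061086, chromosome 11, 104550663 to 104595753, plus strand), a log2 fold change of -3.56 ± 0.11 (edgeR adjusted p = 3.11e-11). The light chain Myl1 stood at 691 ± 85.1 CPM in DMSO and 100.4 ± 6.35 CPM in sal003, the Z-disc protein Actn2 at 732 ± 99.4 CPM in DMSO and 85.7 ± 10.4 CPM in sal003, and the M-band protein Myom1 at 342 ± 23.6 CPM in DMSO and 63.5 ± 4.92 CPM in sal003.

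Genes of myogenic commitment and fusion moved with it: of 31 tested, 25 fell and 1 rose (1 higher and 26 lower adjusted over the list alone), with a median of -1.31 (camera adjusted p = 1.72e-45; 0.00133 with an estimated correlation). Myog, the transcription factor of terminal differentiation, went from 2634 ± 248 to 870.3 ± 66.0 CPM (ENSMUSG00000026459, chromosome 1, 134289989 to 134292548, plus strand), a log2 fold change of -1.60 ± 0.09 (edgeR adjusted p = 4.58e-09). Cdkn1a, the p21 inhibitor of cyclin-dependent kinases, went from 439 ± 31.7 to 122 ± 15.7 CPM (-1.85 ± 0.10). Hfe2, which encodes hemojuvelin, had a log2 fold change of -2.72 ± 0.12, Mybph of -2.57 ± 0.12 and the thin filament nucleator Lmod3 of -2.46 ± 0.13. Mybph and Lmod3 belong to the contractile apparatus, so the fall of this list is not wholly separate from that of the sarcomere list. The member that rose was Igfbp5, at 0.78 ± 0.10, named after its value was seen. Myod1, the determination factor that acts upstream of Myog, stood at 896 ± 85.8 CPM in DMSO and 892 ± 52.3 CPM in sal003 and its log2 fold change of -0.01 ± 0.08 did not pass the test (adjusted p = 0.975).

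The satellite cell identity list was split. Of 41 genes tested 2 rose, Pax7 and Met, and 17 fell (3 higher and 17 lower adjusted over the list alone), and the median was -0.17 (camera adjusted p = 0.0174). That call was lost with an estimated correlation (adjusted p = 0.0826). Pax7, the transcription factor that marks satellite cells, went from 72.1 ± 6.74 to 97.2 ± 2.54 CPM (log2 fold change 0.43 ± 0.10, edgeR adjusted p = 0.00539), and Met, the receptor of hepatocyte growth factor, from 131 ± 22.1 to 297 ± 15.4 CPM (1.18 ± 0.11). Pax3 (0.33 ± 0.19, adjusted p = 0.259) and Myf5 (0.38 ± 0.19, adjusted p = 0.190) had positive estimates that did not pass. The members that fell with the lowest p were Ncam1 (-0.98 ± 0.07) and Cdh15 (-0.92 ± 0.10), adhesion molecules that differentiating myoblasts also carry, and Cdkn1c (-2.95 ± 0.24), an inhibitor of the cell cycle. In the Notch list, 18 of 25 genes could be tested, 3 fell and 0 rose (0 higher and 2 lower adjusted over the list alone). The receptors Notch3 (-0.92 ± 0.14) and Notch1 (-0.67 ± 0.12) were among those 3. The third, Heyl (-0.73 ± 0.25, adjusted p = 0.0485), was lost in 6 of the 8 fits without 1 library (adjusted p up to 0.150), and the list as a whole was not called (median -0.08, camera adjusted p = 0.633).

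Because sal003 is an inhibitor of eIF2α dephosphorylation, transcripts that rise when ATF4 or CHOP are made were fixed as a list in advance. They were not higher as a group. Of 42 tested, 3 rose, 13 fell and 26 did not pass (3 higher and 13 lower adjusted over the list alone), with a median of -0.26 (camera adjusted p = 0.0236). The call toward lower values was lost with an estimated correlation (adjusted p = 0.255), without DMSO replicate 2 (adjusted p = 0.1004) and without members that other lists also hold (median -0.0792, adjusted p = 0.142). Atf4 stood at 317 ± 20.2 CPM in DMSO and 270.0 ± 31.4 CPM in sal003 (-0.23 ± 0.10, edgeR adjusted p = 0.104). Its estimate passed with the stricter filter (adjusted p = 0.0363) and with limma-voom (0.0409), and was -0.15 without sal003 replicate 4. Ddit3, which encodes CHOP, stood at 5.43 ± 2.79 CPM in DMSO and 2.63 ± 0.657 CPM in sal003 (-1.05 ± 0.48, adjusted p = 0.145). Fgf21, a secreted metabolic hormone, went from 27.7 ± 7.17 to 0.667 ± 0.347 CPM (-5.37 ± 0.38, adjusted p = 5.11e-08). Gpt2, a transaminase (-0.72 ± 0.09), and Slc7a5, a subunit of the large neutral amino acid transporter (-0.68 ± 0.10), also fell.

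Among 20 genes of eIF2, its kinases and its phosphatases, 2 rose and 1 fell (2 higher and 1 lower adjusted over the list alone; median 0.17, camera adjusted p = 0.311). The stress-induced phosphatase subunit Ppp1r15a fell, from 44.8 ± 9.55 to 25.9 ± 5.16 CPM (-0.79 ± 0.18, edgeR adjusted p = 0.00452). Its constitutive counterpart Ppp1r15b had a log2 fold change of 0.11 ± 0.12 (adjusted p = 0.609). Eif2s1, which encodes eIF2α itself, had 0.33 ± 0.12 (adjusted p = 0.0711) and passed without DMSO replicate 2, at 0.48 (adjusted p = 0.000382), without a filter (0.0308), with limma-voom (0.000463) and among protein-coding genes (0.0343). Eif5, the GTPase activator of eIF2, rose (0.90 ± 0.10), and so did the kinase Eif2ak4 (0.49 ± 0.15, adjusted p = 0.0256), whose call was lost in 4 of the 8 fits that left out 1 library: adjusted p = 0.0647 without DMSO replicate 1, 0.0577 without sal003 replicate 1, 0.0953 without sal003 replicate 2 and 0.0875 without sal003 replicate 3. Of 20 aminoacyl-tRNA synthetases, 1 rose, Vars (0.53 ± 0.10), and 2 fell (1 higher and 2 lower adjusted over the list alone), Lars (-0.30 ± 0.08; adjusted p = 0.0529 without sal003 replicate 2) and Cars (-0.28 ± 0.09), whose call was lost in 6 of the 8 fits without 1 library (adjusted p up to 0.116). That list was not called (median -0.12, camera adjusted p = 0.809). Of 30 genes of the list unfolded protein response and ER chaperones 2 rose and 10 fell (3 higher and 12 lower adjusted over the list alone; median -0.18, camera adjusted p = 0.0468). This call was lost with an estimated correlation (adjusted p = 0.237) and, among the fits that left out 1 library, without DMSO replicate 2 (0.0616), 3 (0.0922) or 4 (0.0681) and without sal003 replicate 2 (0.0722) or 3 (0.0775). It was lost too with the stricter filter (0.128), with halved counts (0.0539) and among protein-coding genes (0.121), and the median without DMSO replicate 2 was -0.11. Herpud1, a factor of endoplasmic reticulum degradation, fell (-1.24 ± 0.10), as did the sensor Atf6 (-0.89 ± 0.09), while Edem1 rose (0.70 ± 0.15).

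Targets of p53 fell together: 19 of 27 tested were lower and 0 higher (20 lower adjusted over the list alone), with a median of -1.02 (camera adjusted p = 2.70e-13; 0.00133 with an estimated correlation). Beside Cdkn1a, which 2 further lists hold, they included the receptor Eda2r (-2.44 ± 0.16) and the apoptosis gene Pmaip1 (-1.74 ± 0.14). Of 79 cytosolic ribosomal protein genes 12 rose and 0 fell (6 higher and 0 lower adjusted over the list alone), with a median of 0.21. The camera adjusted p was 0.00195 and was 0.333 with an estimated correlation. The lowest p in the list were those of Rpl3 (0.55 ± 0.09) and Rpl6 (0.49 ± 0.10), but many of these genes have near-identical pseudogene copies, which leaves their values uncertain.

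Several metabolic and stress lists were not called, and all but the interferon list moved both ways. Glycolysis had 4 genes higher and 5 lower of 21 (5 higher and 7 lower adjusted over the list alone; median -0.12, camera adjusted p = 0.351), with the muscle phosphofructokinase Pfkm at -2.05 ± 0.10, Aldoa at -0.68 ± 0.07 and Hk2 at 0.97 ± 0.16. Heat shock proteins had 6 higher and 4 lower of 20 (6 higher and 4 lower adjusted over the list alone; median 0.10, camera adjusted p = 0.880), where the small heat shock proteins Cryab (-1.95 ± 0.12) and Hspb8 (-1.63 ± 0.10) fell, while Hsp90aa1 (0.64 ± 0.11) and Hspe1 (0.89 ± 0.15) rose. NRF2 targets had 8 higher, with Ftl1 (0.73 ± 0.08) and G6pdx (0.66 ± 0.09) among them, and 4 lower of 24 (10 higher and 6 lower adjusted over the list alone; median 0.18, camera adjusted p = 0.109). That list was called toward higher values without DMSO replicate 2 (median 0.24, adjusted p = 0.0441). In cholesterol synthesis 3 rose and 2 fell of 26 (3 higher and 2 lower adjusted over the list alone; median 0.13, camera adjusted p = 0.919), with Ebp at -1.17 ± 0.15, Sqle at 0.69 ± 0.16 and Stard4 at 0.94 ± 0.24. Nuclear genes of oxidative phosphorylation had 2 higher and 4 lower of 55 (2 higher and 4 lower adjusted over the list alone; median -0.06, camera adjusted p = 0.656), with Ndufa9 at -0.58 ± 0.11 and Sdhd at 0.57 ± 0.15, which was lost without sal003 replicate 1 (adjusted p = 0.0522). Of 18 interferon response genes tested 0 rose and 1 fell, H2-K1 (-0.70 ± 0.20; 0 higher and 0 lower adjusted over the list alone; median -0.43, camera adjusted p = 0.782), a call that was lost without DMSO replicate 1 (adjusted p = 0.0525), sal003 replicate 3 (0.0728) or sal003 replicate 4 (0.0586). The median of the interferon list was -0.16 without DMSO replicate 4. Of 11 cytokine genes 2 rose, Csf1 (0.52 ± 0.09) and Cxcl12 (0.59 ± 0.19), and 1 fell, Il1b (-2.73 ± 0.60; 2 higher and 1 lower adjusted over the list alone; median -0.19, camera adjusted p = 0.919). The Cxcl12 call was lost in 5 of the 8 fits without 1 library (adjusted p up to 0.139). The median, mean and camera direction differed in sign for the glycolysis, heat shock, cytokine and immune lists.

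In the extracellular matrix list 6 genes rose and 12 fell of 42 (9 higher and 16 lower adjusted over the list alone; median -0.16, camera adjusted p = 0.0314). With an estimated correlation the adjusted p was 0.0969, and the call was also lost without DMSO replicate 2 (0.0616) or sal003 replicate 1 (0.0528, median -0.0818), with the stricter filter (0.107) and among protein-coding genes (0.0933). The basement membrane protein Nid2 went from 142 ± 32.0 to 23.5 ± 1.20 CPM (-2.60 ± 0.14), and Thbs1, thrombospondin 1, had a log2 fold change of -0.83 ± 0.09.

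Most markers of other cell types did not pass the filter on counts. Of 22 fibro-adipogenic markers 8 could be tested, 0 rose and 2 fell (0 higher and 2 lower adjusted over the list alone), Gsn (-0.57 ± 0.13) and Tcf4 (-0.35 ± 0.10), and the list was not called (median -0.68, camera adjusted p = 0.293). The Tcf4 call was lost in 5 of the 8 fits that left out 1 library, with adjusted p of 0.0882 and 0.0583 without DMSO replicate 3 and 4 and of 0.0616, 0.0609 and 0.0537 without sal003 replicate 1, 2 and 4. This Tcf4, on chromosome 18, is not Tcf7l2, the fibroblast marker whose protein is also called TCF4. Its call therefore gives no evidence on fibro-adipogenic cells. Of 16 endothelial markers 7 were tested, 0 rose and 1 fell, Vwf (-1.48 ± 0.34; 0 higher and 1 lower adjusted over the list alone; median -0.63, camera adjusted p = 0.750). Of 24 immune markers 6 were tested and 0 passed the gene test in edgeR over all genes or adjusted over the list alone (median 0.09, camera adjusted p = 0.997; median 0.61 without sal003 replicate 4). Among tenocyte, mesothelial, adipocyte and erythroid markers 5 of 22 were tested, 0 rose and 2 fell (0 higher and 2 lower adjusted over the list alone), Scx (-0.92 ± 0.13) and Msln (-1.33 ± 0.39; adjusted p = 0.0515 without sal003 replicate 4), with a median of -0.66 (camera adjusted p = 0.405). Smooth muscle and pericyte markers fell with the sarcomere genes: 7 of 9 tested were lower and 0 higher (0 higher and 7 lower adjusted over the list alone), with a median of -1.10 (camera adjusted p = 5.08e-09; 0.00904 with an estimated correlation). Acta2, smooth muscle actin, which myoblasts also express, stood at 1545 ± 64.2 CPM in DMSO and 470.4 ± 84.9 CPM in sal003, and the potassium channel regulator Abcc9 at 77.2 ± 3.83 CPM in DMSO and 15.2 ± 1.14 CPM in sal003. Notch3, another member, is also held by the satellite cell identity and Notch lists. The fall of this list therefore does not show that pericytes were present or lost. Of 12 Schwann cell markers 5 were tested, 0 rose and 2 fell (0 higher and 2 lower adjusted over the list alone), Erbb3 (-1.56 ± 0.09) and Ngfr (-0.78 ± 0.12), which muscle cells can express too (median -0.41, camera adjusted p = 0.0229; 0.0969 with an estimated correlation). The median of the Schwann list was 0.19 without DMSO replicate 4, and its adjusted p was 0.0519 among protein-coding genes.

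Of the lists kept as signs of sample handling, the 15 mitochondrial genome transcripts had 0 higher and 2 lower (0 higher and 2 lower adjusted over the list alone; median -0.09, camera adjusted p = 0.750). The 2 were mt-Nd5 (-0.42 ± 0.09) and mt-Nd4l (-0.53 ± 0.15), and the call on mt-Nd4l was lost in 3 of the 8 fits without 1 library (adjusted p up to 0.0713). Mitochondrial genes took 5.24% ± 1.07 of counts in DMSO and 5.62% ± 0.190 in sal003 (SD, n = 4). The ribosomal RNA mt-Rnr2 alone took 4.06% of the pooled DMSO counts and 4.26% of the pooled sal003 counts. Because ribosomal and mitochondrial RNA had been depleted, this share cannot be read as a sign of handling alone. Among 21 nuclear-retained and immediate early transcripts 1 rose and 10 fell (1 higher and 11 lower adjusted over the list alone; median -0.78, camera adjusted p = 0.000268; 0.0969 with an estimated correlation). The lowest p among them were those of the early transcription factor Klf4 (-1.87 ± 0.15) and the imprinted long non-coding RNA Meg3 (-1.53 ± 0.13), which both fell.

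**Figure D3:**
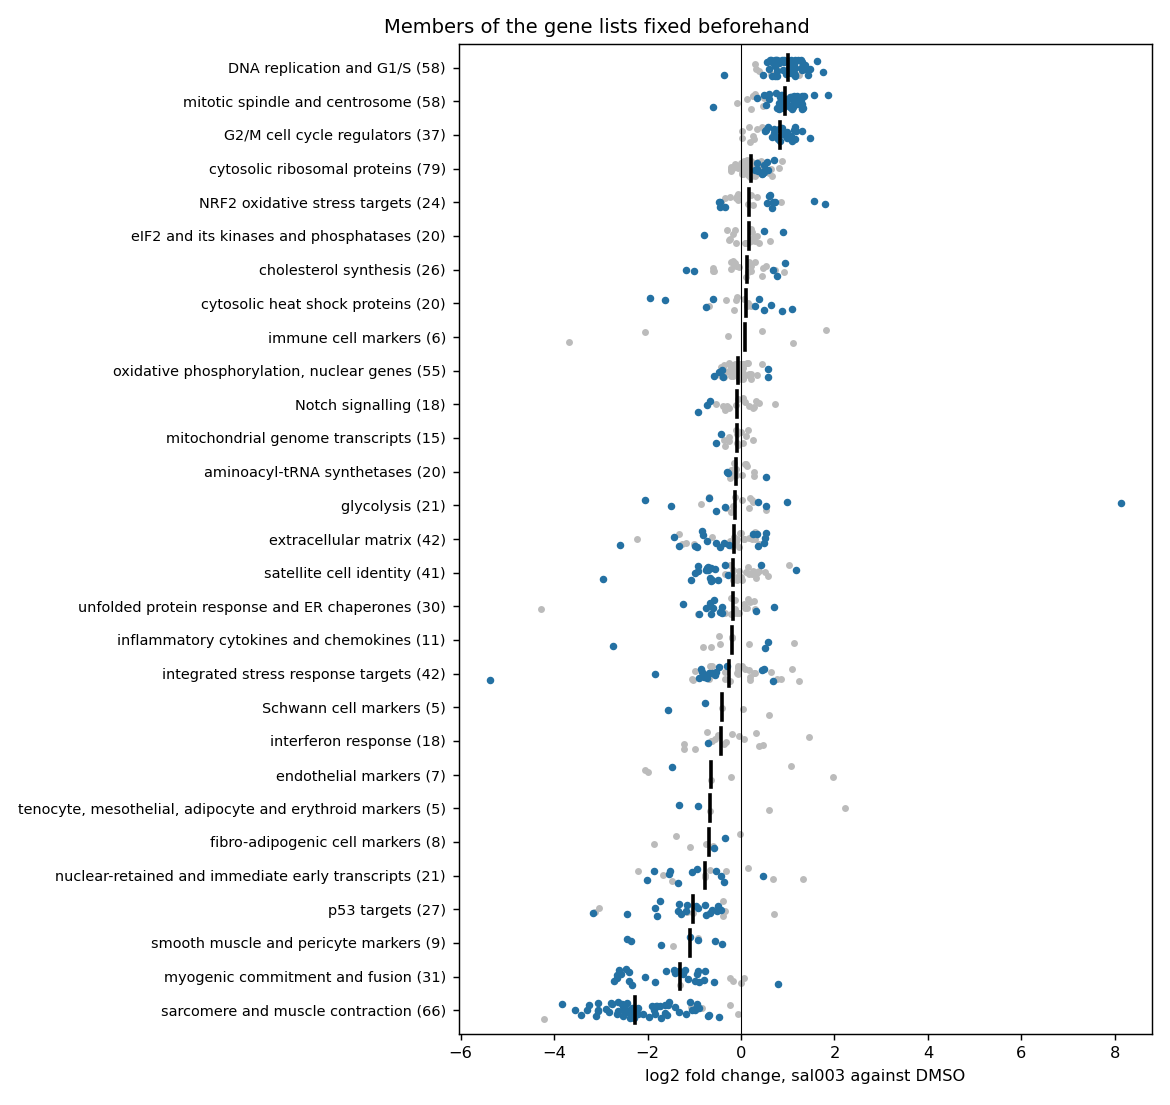
Log2 fold change of sal003 against DMSO for each tested member of the 29 gene lists fixed in advance, with the number of tested members in brackets, genes at an edgeR adjusted p below 0.05 in blue, the others in grey, and the list median as a black bar. Replication, spindle and G2/M genes lie to the right of 0 and sarcomere and commitment genes to the left; the point beyond 8 is a glycolysis gene with 0 counts in the DMSO libraries, so that its position depends on the prior count.

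Among genes at or above the median expression of 14.5 CPM whose groups did not overlap, the largest increases included Kif18a (1.86 ± 0.24), Cd24a (1.76 ± 0.19), Chaf1b (1.75 ± 0.26), Sfxn1 (1.72 ± 0.22), Hells (1.71 ± 0.13), Cdc6 (1.63 ± 0.15) and Hist1h1b (1.56 ± 0.15). Kif18a is a mitotic kinesin, Chaf1b a chromatin assembly factor, Hells a chromatin remodeller, Cdc6 a replication licensing factor and Hist1h1b a linker histone. Cd24a, a cell surface glycoprotein, went from 15.4 ± 4.42 to 52.4 ± 4.98 CPM. The 8 largest decreases were in Frem2 (-3.71 ± 0.20), Slc24a4 (-3.64 ± 0.29), Myl4, Car3 (-3.48 ± 0.27), Capn3 (-3.47 ± 0.24), Aknad1 (-3.41 ± 0.25), Tnfrsf19 (-3.41 ± 0.35) and Grip2 (-3.29 ± 0.28). Frem2, an extracellular matrix protein, went from 150.0 ± 27.9 to 11.5 ± 3.15 CPM, Car3, the carbonic anhydrase of muscle and fat, from 44.8 ± 6.61 to 4.02 ± 1.79 CPM, and Capn3, the calpain of skeletal muscle, from 50.5 ± 7.77 to 4.57 ± 1.55 CPM (SD, n = 4). The edgeR adjusted p of these genes lay at or below 0.000111, the value of Chaf1b.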

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

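The tests for a swapped library, for scaling in the cell cycle and sarcomere lists, for dilution by other cells and for fewer differentiated cells were chosen after the values they use had been seen. Among 228 groups of 4 values examined, 7 had 1 library far from the other 3 for the range of the group (Dixon's ratio), where chance would give about 11.4. The number of genes detected was 14437 in DMSO replicate 2 against 17475 to 18076 in the other DMSO libraries, and the mean Spearman correlation of that library with its own group was 0.947 against 0.967 to 0.968. Ccnd3 was at 384 CPM in DMSO replicate 2 against 305 to 316 CPM, and Heyl at 18.9 CPM in DMSO replicate 4 against 14.8 to 15.2 CPM. Edem1 was at 50.3 CPM in sal003 replicate 1 against 44.9 to 45.7 CPM, and Eif5 at 337.5 CPM in sal003 replicate 2 against 293 to 296 CPM. The TMM factor of sal003 replicate 4 was 1.04 against 1.07 in each of the other sal003 libraries.

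DMSO replicate 2 stood apart from the other libraries. A swapped sal003 library is argued against by the sarcomere genes, whose mean log2 CPM in this library lay 0.20 from the mean of the other DMSO libraries and 1.91 from that of sal003, a difference of 1.71. On the second principal component, however, the library lay at 28.9, nearer to sal003 (34.2 to 56.8) than to the other DMSO libraries (-75.3 to -60.4). Few distinct molecules in the library may account for the lower number of genes, but the test left this open. With the tested genes in 4 sets of 3954 from least to most expressed, the SD of its log2 deviations was 1.68, 2.47, 1.96 and 1.90 times that of the other DMSO libraries, with 1915 genes of the first set at 0 in this library. The bound of 2 was set for the last set alone. Few distinct molecules predicted a deviation near that of the others in the last set and far above it in the first. The ratios did not follow that order. Each other DMSO library was set against fewer libraries than replicate 2 was, which lowers the ratios slightly, so 1.90 cannot be told from the bound.

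Cell cycle lists were higher and the sarcomere list lower in sal003. Scaling set by abundant muscle transcripts as the whole cause is argued against, because one factor moves all genes of a library alike. The spindle and sarcomere medians lay 3.21 apart on the log2 scale, against at most 0.47 in 1000 random pairs of gene sets of the same sizes. This test replaced a first one, the distance of the spindle median from that of all genes under other scalings, which such a factor cannot move. No factor can move the gap either, so it shows only that the 2 lists parted. The gap does not settle how much of the cell cycle rise alone came from scaling, but shares of counts limit it. The sarcomere list took 9.75% of counts in DMSO and 3.05% in sal003. The counts freed could lift other genes only by a small part of the spindle median of 0.93. This argues against scaling by sarcomere transcripts as the main source of that rise. Dilution by cells outside the muscle lineage would lower Myod1 along with the sarcomere genes, but Myod1 lay 2.27 above the sarcomere median. As a hypothesis, the treatment may change either the share of differentiated cells or the muscle transcripts per cell, and these cannot be told apart in bulk libraries: the SD of log2 fold changes over the sarcomere list was 0.89, but no list of genes made only in differentiated cells could be set here. Of the 35 splits of the 8 libraries into 4 and 4, 1, the real one, gave as many as 3594 genes, and the highest of the others gave 0. For the 14 lists called, 1 split gave as many and the highest other split gave 12. This argues against a chance split of the libraries, but it is a weak test. No result can be rarer than 1 in 35, and every other split mixes the conditions, which widens the spread within its groups. A cause other than sal003 that the libraries of a condition share would pass it too.

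Transcripts of the integrated stress response were not higher in sal003, although the compound acts on eIF2α. Scaling stays open: the highest list median over TMM, 2 other scalings and removal of abundant genes was -0.26, but these left the median of all tested genes between -0.0141 and -0.000862, so the test is void. The lower position of the list may rest in part on members that other lists hold: without these 6 members the median of the remaining 36 was -0.0792, between the bounds set for the test. An effect of the treatment on these transcripts at other times was not analysed here and stays open.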

How the results depend on the processing

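The direction and call for Tacc3 (log2 fold change 0.80 to 0.89) were the same in the 18 alternatives that covered single genes. Those for the spindle, commitment and sarcomere lists were the same in the 19 that covered lists. The GC and length fits gave gene counts only. Without the GC trend 1682 genes were higher and 1846 lower, of which 1382 and 1666 were calls of the main fit. Without the length trend these were 1671 and 1871, of which 1573 and 1833 were calls of the main fit. The counts of 1671 higher and 1923 lower genes became 984 higher and 1324 lower (42.6% higher) at an adjusted p of 0.01, and 266 higher and 737 lower against a 1.5-fold change, which are stricter by construction. Scaling moved the share of higher among changed genes from 46.5% to between 45.4% and 46.8%, and the lowest median of all tested genes was -0.0141. Leaving out 1 library gave 1270 to 2219 higher and 1612 to 2252 lower genes. The stress response list (main median -0.26) was not called with an estimated correlation (-0.26, adjusted p = 0.255), without shared members (-0.0792, 0.142) or, chosen after seeing the data, among protein-coding genes (-0.24, 0.0754), and ranged from -0.30 to -0.20 over the fits without 1 library. The satellite cell identity list was not called with an estimated correlation (-0.17, adjusted p = 0.0826) or among protein-coding genes (-0.15, adjusted p = 0.0603), and ranged from -0.21 to -0.0969 over the fits without 1 library. Of the 24 secondary lists, 9 were called at first, 4 with an estimated correlation and 15 with fry, which asks another question. The mean within-group Pearson correlation of log2 CPM fell from 0.926 ± 0.0288 (SD over pairs) to 0.255 over the 500 most variable genes with a prior count of 0.5.

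Signs turned for results that were close to 0 or not called, and for the Schwann list. Myod1 (main -0.01) was at 0.00533 without a filter, 0.0524 with limma-voom and 0.0156 among protein-coding genes, and ranged from -0.0330 to 0.0731 without 1 library. The immune list was at -0.31 without a filter, where Cars (adjusted p = 0.0676) and Heyl (0.0513) did not pass. With the stricter filter the cholesterol list was at -0.13 and the cytokine list at 0.48. With the replicate block the list of Schwann cell markers was at 0.0501 and that of mitochondrial genome transcripts at 0.0164. Without 1 library the ranges were -0.81 to 0.19 for the Schwann list, -0.24 to 0.14 for the mitochondrial list, -0.24 to 0.0407 for the cytokine list, -0.16 to 0.0389 for glycolysis and -0.16 to 0.00854 for Tacc1. The medians of other lists moved by over 1.5 times in at least 1 such fit without turning, with ranges over those fits of -0.51 to -0.16 for interferon, 0.0593 to 0.61 for immune, -0.98 to -0.42 for endothelial, -1.09 to -0.73 for tenocyte and related, -0.14 to -0.0395 for Notch, -0.12 to -0.0253 for oxidative phosphorylation, 0.0611 to 0.14 for heat shock, 0.12 to 0.24 for NRF2, 0.0497 to 0.18 for cholesterol, -0.20 to -0.11 for unfolded protein response and -0.24 to -0.0818 for matrix genes; so did Ppp1r15b (0.0475 to 0.24), Atf4 (-0.28 to -0.15) and H19 (-0.22 to -0.0954). With limma-voom Ddit3 was at -0.61. The cause was not tested. Whether replicate numbers pair the libraries was not settled. Of the 4 same-numbered pairs 2 had a correlation of deviations over 0.1, and 2 of 4 DMSO libraries correlated best with their own number. These values were not compared with what chance gives. The replicate block gave 1660 higher and 1770 lower genes, and the unfolded protein response list was not called there (adjusted p = 0.0528), while Eif2ak4 (0.0523), Cars (0.0690) and Cxcl12 (0.0616) did not pass and Eif2s1 did (0.0314). Of 39017 genes 15816 had enough counts to be tested and 17215 had no count in any library; whether depth limits the fold changes of tested genes was not tested.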

Other observations

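The lists in this part, and its genes other than Meg3, were chosen after the data were seen, and their adjusted p, over these 3 lists, are descriptions. The RNA was not selected by poly(A) tail, so replication-dependent histone transcripts, which lack one, could be read. Of 65 of these genes tested, 42 were higher in sal003 and 0 lower, with a median log2 fold change of 0.97 (camera adjusted p = 2.25e-18; 0.0609 with an estimated correlation, which ends the call). Their near-identical copies make the values of single genes uncertain. Of 38 genes of ribosome assembly in the nucleolus 25 were higher and 1 lower, with a median of 0.57 (camera adjusted p = 1.42e-10; 0.00301 with an estimated correlation). Nucleolin, Ncl, went from 736 ± 134 to 1650.3 ± 43.5 CPM, and nucleophosmin, Npm1, from 405 ± 72.8 to 887 ± 55.9 CPM (SD, n = 4).

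Of 25 imprinted genes tested, 11 were lower and 3 higher in sal003, with a median of -0.62 (camera adjusted p = 6.00e-06; 0.00599 with an estimated correlation). At the Dlk1 to Meg3 locus on chromosome 12, the long non-coding RNAs Meg3 (109541001 to 109571726, -1.53 ± 0.13), Rian (109603940 to 109661716, -1.45 ± 0.15) and Mirg (109729764 to 109749460, -1.53 ± 0.20), all on the plus strand, were lower by similar amounts. Dlk1 itself, at 4.63 ± 4.94 CPM in DMSO, had -3.27 ± 1.08 (edgeR adjusted p = 0.0410), a call that was lost without DMSO replicate 2 (-2.19, adjusted p = 0.146), DMSO replicate 3 (0.0668), sal003 replicate 2 (0.117) or sal003 replicate 3 (0.116). On chromosome 7, Igf2 had a log2 fold change of -0.91 ± 0.07 (adjusted p = 1.99e-07). The neighbour of Igf2, H19, one of the most abundant transcripts at 14183 ± 1688 CPM in DMSO, had -0.19 ± 0.08 (adjusted p = 0.134) and passed without DMSO replicate 2 (-0.22, adjusted p = 0.0122) and with limma-voom (0.0423). The gene of the microRNA inside H19 was counted as well, so reads there may be counted for both or split, which was not tested.

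Fst, which encodes follistatin, an extracellular antagonist of myostatin and activin, had the lowest p after Myl4, from 252 ± 17.2 to 30.4 ± 3.23 CPM (-3.05 ± 0.11, edgeR adjusted p = 9.41e-11), with all 4 sal003 libraries below all 4 DMSO libraries.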
